A study of Mus musculus with 6 samples.

How the data were processed

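The series holds 6 RNA sequencing libraries of NKT1 iNKT cells sorted by flow cytometry from BALB/c thymus, 3 CD4-positive and 3 CD4-negative, grouped and numbered by their titles. RNA was isolated with the RNeasy Plus Micro kit and sequenced in paired ends on a HiSeq4000 after TruSeq stranded mRNA preparation, per the labels' protocols. STAR, Picard and RSEM and the mouse build mm10 are named, per the submitters' processing notes, without versions, parameters or roles. The annotation used for counting and its strand setting are not given in the sources used here. The authors deposited a single table of estimated counts per gene, which were not normalised (RSEM, a tool that estimates such counts, is named in the submitters' processing notes), with a versioned Ensembl identifier and a symbol for each of 47643 genes. All 6 columns were matched to samples by the library names in the labels. Between 6.23% and 8.68% of all 47643 genes had a fractional value in a library (further than 1e-06 from a whole number), as arises where reads are shared between genes. Only 13787 to 16267 genes had a count in a library, so the share among those was higher. Values were rounded to whole numbers before testing. Coordinates and biotypes come from GENCODE release M21 (GRCm38, the assembly of mm10), in which 47224 of the identifiers were found when their version was ignored.

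Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these libraries, which may in part be technical. Libraries of a group were compared for duplicates by a chi-square test of their counts over genes with at least 10 counts. The statistic per degree of freedom was 55.6 to 400.5, where sampling noise alone gives about 1. This argues against reruns of the same library, and all 6 libraries were kept. The test cannot tell separate samples from separate preparations of the same sample. The depth of 40480463 to 53145848 counts makes 1 count worth 0.0185 to 0.0261 CPM, and a count of 0 allows up to 3 counts, or 0.0555 to 0.0783 CPM, by counting error only.

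The comparison was fitted in R 4.3.3 with edgeR 4.0.16: genes kept by filterByExpr (12760), TMM scaling, robust dispersions (common dispersion 0.0994), the robust quasi-likelihood F test on group alone, 2-sided, and Benjamini-Hochberg adjustment at 0.05. No replicate block was in the design. The SE of a log2 fold change was derived from its F statistic. The 22 gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 22 lists, for lists of at least 5 tested members; the estimated-correlation form and fry were alternatives. For each list the members past the test over all genes and adjusted over the list alone were counted. The NK cell, B cell, myeloid, gamma-delta T cell, thymocyte, regulatory T cell and stroma lists hold markers of other cells that the sort could contain.

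Genes were named by a rule fixed before the data were examined, as were the lists, the test and the alternatives other than those said to be added. It takes Cd4 as a label check, 11 genes of lineage and effector programmes whatever their result (some genes are not reported here), and, in each direction, up to 12 genes with the largest change among those past the test with non-overlapping groups and a mean of at least 5 CPM in the higher group. Cd4, predicted genes, pseudogenes and receptor segments are left out of that part, which gave 7 higher genes and 12 of 17 lower genes. From each list it takes up to 2 called members per direction, or else the 2 with the smallest p. Members that passed only adjusted over the list alone were named after their values were seen. So were the Y-linked genes, Xist, Fos, Foxp3, Rag1, Rag2, Dntt, Ptcra and Igkc.

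Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0 (on all genes with a count, without the filter on low counts), limma-voom, no filter on low counts, a mean of at least 5 CPM, the replicate number as a block, the library naming scheme as a batch term, thresholds of 0.01 and of 2-fold, and each of the 6 libraries left out in turn. Added after seeing the data were limma-voom with sample quality weights, DESeq2 on the filtered genes, leaving out both libraries of a replicate number, and the list counts without CD4-negative replicate 3. The tests were run first on simulated counts for the CD4-positive against CD4-negative comparison with 200 changed genes and a shifted list of further genes. The changed and the listed genes all had a mean of at least 5 CPM, so recovery at lower levels is not shown. Over 12474 genes edgeR recovered 21.7% of the 2-fold and 98.0% of the 4-fold changes, with 5 false among 129 calls (3.88%). limma-voom recovered 22.5% and 97.0% (4 false among 128, 3.12%), and with quality weights 23.3% and 98.0% (4 false among 130, 3.08%), in simulated libraries of which none was made to stand apart. DESeq2, over 12760 genes, recovered 58.3% and 100% with 34 false among 204 calls (16.7%). The shifted list gave a camera p of 2.6e-25 and the unshifted list 0.371. Genes were simulated independently of each other, so this does not show how often camera falsely calls lists of correlated genes.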

Results

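Invariant natural killer T (iNKT) cells are T cells with a nearly fixed T cell receptor that recognises lipids presented by CD1d, and NKT1 is the subset that expresses the transcription factor T-bet. Polyadenylated RNA was sequenced from NKT1 cells sorted from the thymus of wild-type BALB/c mice, as 3 libraries of CD4-positive cells and 3 libraries of CD4-negative cells. The totals of estimated counts were 49314314, 50756279 and 51081385 in CD4-positive replicates 1, 2 and 3 and 45841842, 53145848 and 40480463 in CD4-negative replicates 1, 2 and 3. Of 47643 genes in the table, 12760 had enough counts to be tested. Levels are given as TMM-scaled CPM (counts relative to the library total), mean ± SD with n = 3 per group, and log2 fold changes as CD4-positive minus CD4-negative.

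The first principal component held 46.3% of the variance and set CD4-negative replicate 3 (score -90.2) apart from the other libraries, which lay between -2.31 and 32.2. On the third component, with 17.9% of the variance, the CD4-positive libraries had scores of 1.46 to 37.2 and the CD4-negative libraries scores of -31.5 to -8.75. CD4-negative replicate 3 had counts for 13787 genes, against 15293 to 16267 in the other libraries, and its mean correlation with them was 0.944, against 0.963 to 0.970. Its share of mitochondrial counts was 1.33%, close to the 1.35% of CD4-positive replicate 1, while the other libraries had 3.51% to 5.19%. Both replicate 1 libraries held transcripts of Y-linked genes (466 counts in the CD4-positive and 523 in the CD4-negative library over Ddx3y, Eif2s3y, Kdm5d and Uty), and no other library had more than 1 such count. Xist, a transcript of female cells, stood at 124 and 119 CPM in these libraries and at 119 to 178 CPM in the others. The replicate 1 libraries were thus not of male cells alone.

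**Figure D1:**
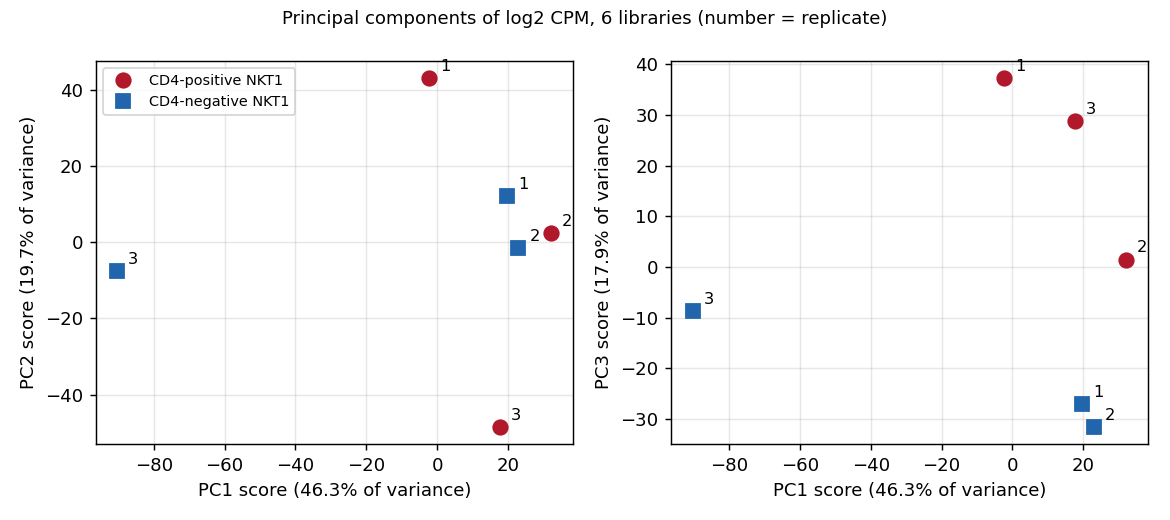
Scores of the 6 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2 CPM, with circles for CD4-positive and squares for CD4-negative libraries and the replicate number beside each point. CD4-negative replicate 3 lies at -90.2 on component 1, and component 3 places the CD4-positive libraries (1.46 to 37.2) above the CD4-negative libraries (-31.5 to -8.75).

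The comparison of CD4-positive with CD4-negative NKT1 cells asked which transcripts differ between the subsets that carry or lack the CD4 coreceptor. Cd4, the sort marker, checks the labels: it stood at 453 ± 53.7 CPM in CD4-positive and 22.7 ± 16.2 CPM in CD4-negative libraries, a difference of 4.32 on the log2 scale (SE 0.52, adjusted p = 0.0330). The single CD4-negative libraries held 16.0, 10.9 and 41.2 CPM of Cd4 (chromosome 6, 124864692 to 124888221, GRCm38). By edgeR's quasi-likelihood test 27 genes differed at an adjusted p under 0.05, of which 9 were higher in CD4-positive cells, Cd4 included, and 18 were lower. All 27 differed by at least 2-fold and had non-overlapping groups. Over all tested genes 1201 had non-overlapping groups, or 9.41%, where chance gives 10% for 3 against 3 libraries.

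CD4-positive NKT1 cells had higher levels of Ccr4, the receptor for the chemokines CCL17 and CCL22, which stood at 25.3 ± 5.10 against 3.40 ± 0.97 CPM, a 7.47-fold difference (log2 2.90, SE 0.27, adjusted p = 0.0214). Izumo1r, which encodes folate receptor 4, a surface protein known from regulatory and anergic T cells, rose 4.38-fold, from 52.6 ± 11.2 to 230 ± 50.3 CPM (adjusted p = 0.0298). Ikzf2, which encodes the transcription factor Helios, rose 2.41-fold, from 14.3 ± 0.35 to 34.6 ± 2.0 CPM (adjusted p = 0.0304). The other named genes that were higher were Sp6, a zinc-finger transcription factor (log2 1.86), Asb2, a subunit of a ubiquitin ligase (1.74), Chst15, a sulfotransferase of chondroitin sulfate (1.67), and Atp8a2, a phospholipid flippase (1.44). Sh3gl3, outside the rule for named genes and listed after its values were seen, passed at a low level (4.90 ± 0.50 against 0.84 ± 0.31 CPM, log2 2.53). Ccr4 lies on chromosome 9 from 114490316 to 114504916, Izumo1r on chromosome 9 from 14885814 to 14903949 and Ikzf2 on chromosome 1 from 69531214 to 69687245.

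The genes lower in CD4-positive cells were led in p by Ccl5, a chemokine made by effector T cells and NK cells, and Emilin2, an extracellular matrix glycoprotein. Ccl5 stood at 94.7 ± 3.62 CPM in CD4-positive and 460 ± 41.4 CPM in CD4-negative libraries (log2 -2.28, SE 0.15, adjusted p = 0.00522), and Emilin2 at 3.20 ± 0.31 and 20.3 ± 1.32 CPM (log2 -2.66, SE 0.18, adjusted p = 0.00522). Ifitm1, Ifitm2 and Ifitm3, which encode interferon-induced membrane proteins that restrict virus entry, fell by 2.82, 2.0 and 1.36 on the log2 scale. These genes are neighbours on chromosome 7 between 140954837 and 141010770, and Ifitm2 had the highest level of them (55.3 ± 6.22 against 221 ± 48.2 CPM). The tyrosine kinase Syk (log2 -2.61), the serpin Serpinb9b (-2.49), the protein kinase C substrate Plek (-2.22) and the sphingosine 1-phosphate receptor S1pr5 (-2.09) fell too. So did the phospholipid transfer protein Pltp (-2.05), the fatty acid elongase Elovl7 (-1.96), galectin-3 (Lgals3, -1.63) and the semaphorin receptor Nrp2 (-1.59). The other genes that passed were Gm4208, Fam129b, Gramd3, Amica1 and Cd244. Of these Cd244 is named by a fixed list, and the others, like Ifitm3, were named after their values were seen. Gm4208, a long noncoding RNA at 62821355 to 62832370 on the minus strand of chromosome 1, lies just past Nrp2 (62703285 to 62818695, plus strand). The estimated counts of Pltp were fractional in 100% of libraries, those of Sp6 in 83.3%, of Amica1 in 66.7% and of Chst15 in 50%, so part of their reads was shared with other genes.

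**Figure D2:**
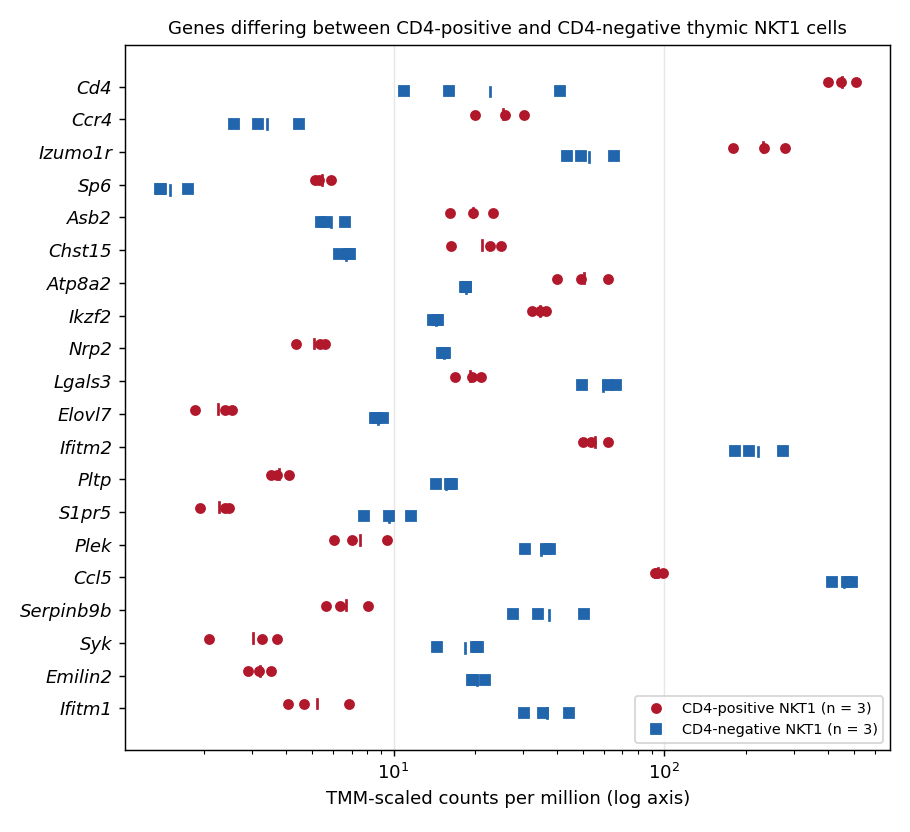
TMM-scaled CPM (log axis) of Cd4 and the 19 named genes that differed, with a circle for each CD4-positive and a square for each CD4-negative library and a vertical bar at each group mean. No gene's groups overlap; Ccl5 averages 94.7 CPM in the CD4-positive and 460 CPM in the CD4-negative libraries.

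The number of genes that passed depended on single libraries and on the design. With the replicate number as a block edgeR called 0 genes, with a smallest adjusted p of 0.0558. At an unadjusted p under 0.05 that fit had 531 genes, where chance gives 638. By edgeR no gene passed when any library but CD4-negative replicate 3 was left out, with 439 to 585 genes at an unadjusted p under 0.05 where chance gives 656 to 661 (567 against 638 by chance with all libraries), while without CD4-negative replicate 3 there were 44 (11 higher, 33 lower), 24 of them among the 27. Replicate 3 of each group follows another library naming scheme, and with that scheme as a batch term 11 genes passed (10 of the 27), while the replicate 1 and 2 libraries alone gave 9 (7 of the 27). The other scheme holds 1 library per group and gives no value of its own.

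The fixed genes of lineage choice and effector programmes did not differ at an adjusted p under 0.05. Among coreceptor genes, Cd8a stood at 26.1 ± 15.5 CPM in CD4-positive and 49.4 ± 25.9 CPM in CD4-negative libraries, and Cd8b1 at 28.9 ± 14.9 and 45.8 ± 34.9 CPM. The coreceptor regulators Zbtb7b (ThPOK) and Runx3 had log2 differences of 0.25 (SE 0.21) and 0.26 (SE 0.31). Zbtb16, which encodes the iNKT master regulator PLZF, stood at 106 ± 40.9 against 61.9 ± 1.82 CPM, with the groups not overlapping (log2 0.78, adjusted p = 0.804). Tbx21 (T-bet) was at 397 ± 51.0 and 437 ± 180 CPM and Gata3 at 129 ± 37.6 and 131 ± 5.86 CPM. Ifng, which encodes interferon gamma, was at 89.3 ± 85.1 and 157 ± 121 CPM, with the highest value of each group in replicate 1 (188 and 295 CPM). Il4 was low in both groups, 2.15 ± 0.26 against 0.59 ± 0.20 CPM (log2 1.87, SE 0.40, adjusted p = 0.201). Il17a had 1 count in 6 libraries and was not tested.

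Genes of the NKT2 and type 2 list, the programme of IL-4-producing iNKT cells, were higher in CD4-positive cells as a set (camera adjusted p = 1.95e-11; adjusted p = 0.0325 with an estimated correlation). Of 19 tested members 2 passed over all genes, Ccr4 and Izumo1r, and 7 adjusted over the list alone, all higher. The others among these were the receptor Slamf6 (39.5 ± 2.96 against 15.3 ± 3.13 CPM), the transcription factor Maf (164 ± 27.0 against 82.9 ± 6.69 CPM), the costimulatory receptor Icos (213 ± 18.8 against 130 ± 3.17 CPM), Il4 and Plac8. The median log2 difference of the list was 0.78. Gata3, the regulator for which the type 2 programme is best known, is a member and differed by -0.03. The set test does not tell a type 2 programme in NKT1 cells from NKT2 cells in the CD4-positive sort, which was not tested.

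Regulatory T cell markers were higher as a set (camera adjusted p = 6.59e-05), with 2 of 9 members past the test over all genes, Izumo1r and Ikzf2, and 4 adjusted over the list alone; the set's adjusted p = 0.0872 with an estimated correlation. Foxp3, the lineage factor of regulatory T cells, was at 0.47 ± 0.22 and 0.61 ± 0.55 CPM. Without CD4-negative replicate 2 the set had an adjusted p of 0.0672. Costimulatory and inhibitory receptors and ligands were higher as a set (camera adjusted p = 0.00216; adjusted p = 0.0872 with an estimated correlation). None of their 26 tested members passed over all genes, and 6 did adjusted over the list alone, 5 higher and 1 lower. The inhibitory receptor Pdcd1 (PD-1) was at 44.4 ± 7.96 against 22.5 ± 0.29 CPM and the tetraspanin Cd81 at 4.71 ± 1.47 against 1.14 ± 0.38 CPM.

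The CD4 and CD8 lineage regulators were also higher as a set (camera adjusted p = 0.00216; adjusted p = 0.228 with an estimated correlation), with none of 20 members past the test over all genes and 1, Tox, adjusted over the list alone (66.4 ± 11 against 28.4 ± 3.04 CPM). Id3, an inhibitor of E-protein transcription factors, stood at 7.16 ± 3.61 against 2.73 ± 0.81 CPM. Without CD4-negative replicate 3 the set had an adjusted p of 0.104. In the cell cycle list 29 of 30 members had a log2 difference above 0, with a median of 0.39 (camera adjusted p = 2.14e-06; adjusted p = 0.400 with an estimated correlation). No member passed the test, over all genes or adjusted over the list alone; Tk1 (thymidine kinase) was at 8.24 ± 2.39 against 4.35 ± 0.94 CPM and the replication helicase subunit Mcm5 at 155 ± 4.19 against 122 ± 4.41 CPM. Interferon response genes were higher as a set (camera adjusted p = 0.00526; adjusted p = 0.212 with an estimated correlation), with none of 30 members past the test over all genes and 1, Ifi44, adjusted over the list alone (16.4 ± 3.37 against 7.68 ± 0.64 CPM); Iigp1 was at 4.64 ± 1.14 against 1.48 ± 0.80 CPM. This set's adjusted p was 0.0984 without CD4-positive replicate 3 and 0.0932 without CD4-negative replicate 1. The interferon-induced genes Ifitm1, Ifitm2 and Ifitm3 are not in this list and went the other way, lower in CD4-positive cells.

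NK receptor genes were lower in CD4-positive cells as a set (camera adjusted p = 3e-06; adjusted p = 0.0421 with an estimated correlation). Of 29 tested members 1 passed over all genes, Cd244, the receptor 2B4 (15.4 ± 1.23 against 35.5 ± 2.62 CPM, log2 -1.20, adjusted p = 0.0433), and 10 did adjusted over the list alone, 8 lower and 2 higher. The activating receptor Ncr1 (NKp46) stood at 28.6 ± 6.86 against 84.2 ± 9.08 CPM (adjusted p = 0.0545), and the signalling adaptors Fcer1g and Tyrobp at 52.97 ± 4.37 against 102 ± 7.06 CPM and 10.4 ± 2.40 against 25.5 ± 6.73 CPM. The members that were higher adjusted over the list alone were Cd226 (89.1 ± 8.22 against 58.7 ± 9.68 CPM) and Fcgr3 (6.23 ± 0.58 against 3.49 ± 0.62 CPM).

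Cytotoxic granule and killing genes were lower as a set (camera adjusted p = 1.7e-05; adjusted p = 0.0872 with an estimated correlation), with none of 20 members past the test over all genes and 3, all lower, adjusted over the list alone. Gzma, which encodes granzyme A, stood at 163 ± 47.6 CPM in CD4-positive and 1243 ± 621 CPM in CD4-negative libraries (log2 -2.93, SE 0.41, adjusted p = 0.0545). Its CD4-negative values were 1059, 735 and 1935 CPM, the last in the replicate 3 library that stood apart, and without that library its adjusted p was 0.0308. The granzyme B inhibitor Serpinb9 was at 95.5 ± 15.8 against 170 ± 6.27 CPM and perforin (Prf1) at 80.6 ± 13.6 against 147 ± 24.1 CPM. NK cell and innate lymphoid cell (ILC) markers were lower as a set (camera adjusted p = 0.00441; adjusted p = 0.0872 with an estimated correlation), with none of 10 members past the test over all genes and 4 adjusted over the list alone, Ncr1, Gzma, Eomes and Klre1. The median log2 difference was -0.18, with 4 of the 10 members above 0. Ncr1 and Klre1 are also NK receptor members, Gzma is a cytotoxic member and Eomes an NKT1 and type 1 member, so this set is not separate from those lists. Eomes, a T-box transcription factor of NK and memory T cells, stood at 11.7 ± 2.06 against 35.6 ± 11.5 CPM. Without CD4-positive replicate 1 this set's adjusted p was 0.0762.

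Homing and adhesion genes were lower as a set (camera adjusted p = 2.14e-06; adjusted p = 0.0872 with an estimated correlation), with 1 of 30 members, S1pr5, past the test over all genes and 6, all lower, adjusted over the list alone. These included genes of thymic exit and recirculation: the transcription factor Klf2 (102 ± 10.3 against 220 ± 45.9 CPM) and the sphingosine 1-phosphate receptor S1pr1 (13.9 ± 3.96 against 27.0 ± 5.36 CPM). The fractalkine receptor Cx3cr1 was at 10.7 ± 2.72 against 31.2 ± 13.8 CPM. The NKT17 and type 17 list was lower as a set (camera adjusted p = 0.000624; adjusted p = 0.0872 with an estimated correlation), with none of 15 members past the test over all genes and 3 adjusted over the list alone. The overlapping neighbours Tmem176b and Tmem176a stood at 3.15 ± 0.21 against 8.37 ± 2.46 CPM and 2.26 ± 0.63 against 5.71 ± 0.69 CPM, and Nrp1 went the other way (20.3 ± 1.56 against 12.7 ± 2.26 CPM). B cell and plasma cell markers were lower as a set (camera adjusted p = 1.43e-06; adjusted p = 0.0421 with an estimated correlation). Only 5 of the 15 listed genes were tested, the fewest that a list may have. With a mean of at least 5 CPM the list had too few members to be tested. None of the 5 members passed the test over all genes, and 3 did adjusted over the list alone. These were the immunoglobulin constant genes Ighm (60.9 ± 12 against 107 ± 4.94 CPM) and Ighd and the receptor chain Cd79b (0.60 ± 0.24 against 2.26 ± 0.22 CPM), while the immunoglobulin light chain Igkc was at 0.32 ± 0.34 and 0.34 ± 0.24 CPM.

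**Figure D3:**
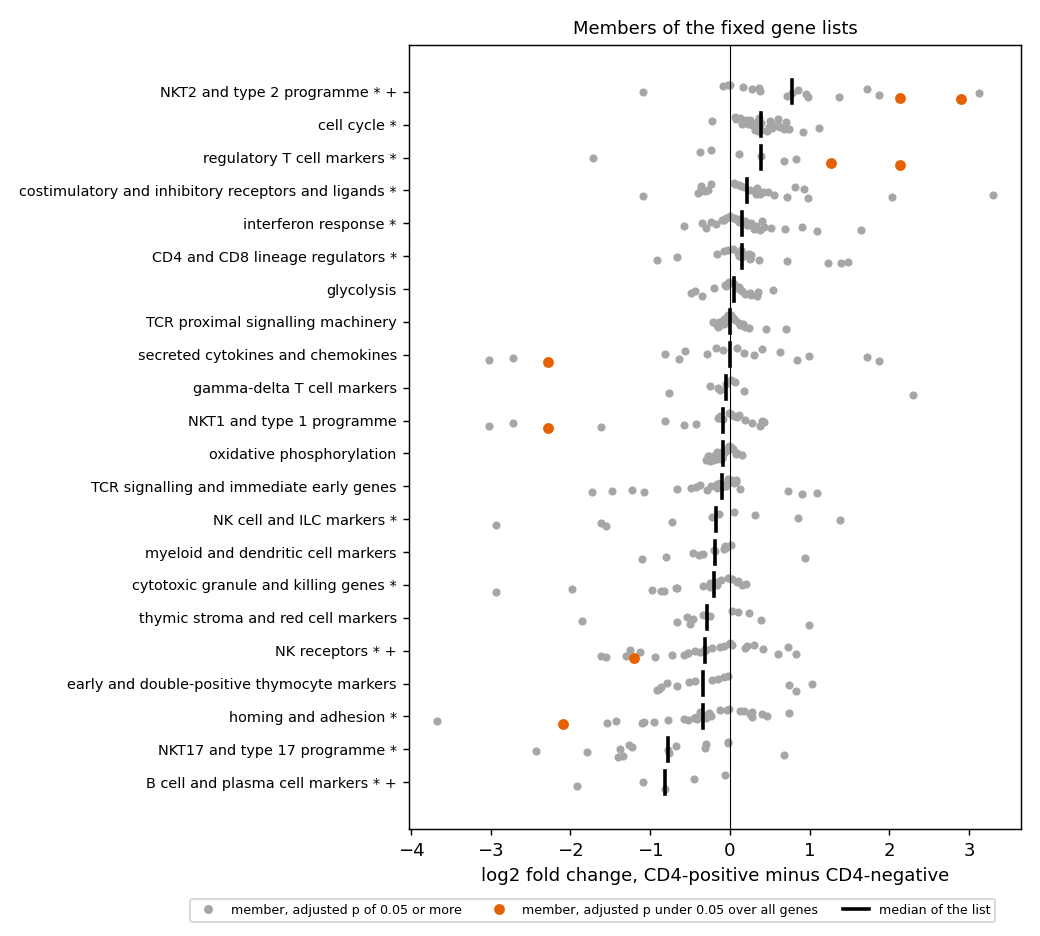
Log2 fold change (CD4-positive minus CD4-negative) of each tested member of the 22 fixed lists, with larger orange points for members past an adjusted p of 0.05 over all genes and a black bar at each list's median. An asterisk marks the 12 lists past the camera test and a plus sign the 3 that also passed with an estimated correlation (NKT2, NK receptors and B cell markers, with medians of 0.78, -0.31 and -0.82).

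The remaining 10 lists did not pass the camera test. The NKT1 and type 1 list had an adjusted p of 0.0671, with 1 of 21 members, Ccl5, past the test over all genes and 2, Ccl5 and Eomes, adjusted over the list alone. Its adjusted p was 0.0371 without CD4-positive replicate 2 and 0.00951 without CD4-negative replicate 3, both with the preset correlation. With an estimated correlation and all libraries its adjusted p was 0.407. Secreted cytokines and chemokines (adjusted p = 0.911) had 1 of 18 members past the test over all genes, Ccl5, and 2 adjusted over the list alone, Ccl5 and Il4, in opposite directions. In the list of T cell receptor (TCR) signalling and immediate early genes (adjusted p = 0.734) the camera test pointed up while the median was -0.10 and the mean -0.20. Of its 28 members none passed over all genes and 1, the receptor-induced factor Egr2 (33.9 ± 1.82 against 18.1 ± 0.19 CPM), adjusted over the list alone; Egr3 was at 20.2 ± 8.16 against 9.45 ± 2.56 CPM. Fos stood at 127 and 419 CPM in CD4-positive and CD4-negative replicate 1 and at 10.1 to 22.9 CPM in the other libraries. Without CD4-negative replicate 1 that list had an adjusted p of 0.000102, in the direction of CD4-positive cells, with the preset correlation of 0.01. Its estimated correlation was 0.594, which gave an adjusted p of 0.942 with all libraries.

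No member passed, over all genes or adjusted over the list alone, among 24 genes of proximal TCR signalling (adjusted p = 0.521), 21 of glycolysis (0.293), 31 of oxidative phosphorylation (0.259), 14 early and double-positive thymocyte markers (0.637) and 12 myeloid and dendritic cell markers (0.230). The members with the smallest p were Slamf1 (log2 0.70) and Sh2d1a (0.46), Hif1a (0.35) and Slc2a1 (-0.36), Ndufb3 (-0.25) and Ndufs7 (-0.21), Il2ra (0.82) and Cd8a (-0.92), and Xcr1 (-1.10) and H2-Aa (0.94). The recombinase gene Rag1 stood at 44.8 and 15.6 CPM in CD4-positive and CD4-negative replicate 3 and at 2.13 to 7.12 CPM in the other libraries. In the same order Dntt stood at 12.8 and 27.1 CPM (0.848 to 4.44 in the others), Rag2 at 2.78 and 4.65 CPM (0.0740 to 0.555) and Ptcra, not tested, at 0.135 and 0.992 CPM (0 to 0.103). Among 9 gamma-delta T cell markers (adjusted p = 0.911; mean 0.14 and median -0.05, with the camera test pointing down) 1, Sox13, passed adjusted over the list alone (8.79 ± 2.01 against 1.79 ± 0.84 CPM), and Cd163l1 was at 4.22 ± 1.59 against 7.14 ± 1.05 CPM. Among 12 thymic stroma and red cell markers (adjusted p = 0.911) 1, the adhesion molecule Pecam1, passed adjusted over the list alone (31.9 ± 1.66 against 16.1 ± 0.75 CPM), and the haemoglobin gene Hbb-bs, whose counts were fractional in 100% of libraries, was at 143 ± 25.2 against 203 ± 72.1 CPM. With a library left out and the preset correlation, glycolysis passed without CD4-positive replicate 2 (adjusted p = 0.0274) or CD4-negative replicate 3 (0.00338) and thymocyte markers without CD4-positive replicate 3 (0.00937) or CD4-negative replicate 2 (0.00702). Oxidative phosphorylation (0.0152) and myeloid markers (0.0406) passed without CD4-negative replicate 2. With all libraries the estimated correlations of these lists were 0.326 for glycolysis, 0.539 for thymocyte markers, 0.422 for oxidative phosphorylation and 0.108 for myeloid markers, which gave adjusted p of 0.887, 0.942, 0.903 and 0.564. The estimated form was not run with a library left out.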

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

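Of the alternatives below, limma-voom with sample quality weights, DESeq2 on the filtered genes and leaving out both libraries of a replicate number were chosen only after the data were seen. All 27 genes kept their direction under every setting in which they were tested (25 of them with a mean of at least 5 CPM). Their groups did not overlap and the settings reuse the same counts, so the direction could hardly change. It lends no further support to the calls. RLE scaling, upper-quartile scaling, limma-voom, the stricter filter and the 2-fold threshold gave 27 to 29 genes. DESeq2 called 162 (64 higher, 98 lower) on the 19410 genes with any count, without the filter, and 191 (79 and 112) on the 12760 filtered genes. Limma-voom with sample quality weights called 180 (79 and 101), no low-count filter 67 (23 and 44), the library naming scheme as batch term 11 (3 and 8) and an adjusted p under 0.01 2 (0 and 2). Without CD4-negative replicate 3 there were 44 (11 and 33), and without CD4-positive replicate 1, 2 or 3 or CD4-negative replicate 1 or 2 edgeR gave 0, with 439 to 585 genes at an unadjusted p under 0.05 (656 to 661 by chance; 567 against 638 with all libraries). Leaving out both libraries of replicate 1, 2 or 3 gave 0, 0 and 9, with 402, 281 and 811 at an unadjusted p under 0.05 (647, 647 and 644 by chance). The omissions so ranged from 0 to 44 genes, 0 to 11 higher and 0 to 33 lower. Fewer libraries leave fewer degrees of freedom; beyond that the cause was not tested.

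With the replicate block edgeR called 0 genes (0 higher, 0 lower), with 531 at an unadjusted p under 0.05 (638 by chance) and a smallest adjusted p of 0.0558; DESeq2, without a block, called 162, or 191 on the filtered genes. Deviations from the group means correlated at -0.0798, 0.343 and 0.0362 for numbers 1, 2 and 3. The rule of 0.1 for every pair was thus not met, and not every library correlated best with its own number. Deviations of 3 libraries from their own mean depend on each other, and CD4-negative replicate 3 stood apart, so the correlations could hardly show pairing. The names of libraries of the same number share an ending or a naming scheme across the groups. The rule does not exclude shared mice: both replicate 1 libraries held Y-linked counts, and thymocyte markers were raised in both replicate 3 libraries. The replicate block also put the NKT1 and type 1 list (adjusted p = 0.00858) and the thymocyte markers (0.0467, lower) past the threshold, and changed no other list call.

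Among the lists, an estimated correlation ended the calls of CD4 and CD8 lineage regulators (0.228), cell cycle (0.400), interferon response (0.212), and costimulatory receptors, cytotoxic genes, homing and adhesion, NK cell and ILC markers, NKT17 and regulatory T cell markers (each 0.0872). fry ended those of lineage regulators (0.129), cell cycle (0.390), homing and adhesion (0.0637), interferon response (0.129) and NKT17 (0.122), and turned gamma-delta T cell markers (0.864) and stroma and red cell markers (0.803) up. A mean of at least 5 CPM ended NKT17 (0.121), put secreted cytokines past the threshold (0.0398) and turned thymocyte and gamma-delta markers up (0.739 each). The B cell, myeloid and stroma lists had fewer than 5 members at that level and were not tested. Upper-quartile scaling put the NKT1 and type 1 list past it (0.0497).

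With libraries left out, adjusted p of the lists by camera with the preset correlation ranged as follows (the estimated form was not run on fewer libraries), each list's library that changes the call being named. Lineage regulators had 0.00109 to 0.104 (without CD4-negative replicate 3), NK cell and ILC markers 0.00351 to 0.121 (0.0762 without CD4-positive replicate 1), and regulatory T cell markers 8.13e-06 to 0.0970 (0.0672 without CD4-negative replicate 2). Interferon response had 0.00137 to 0.0984 (without CD4-positive replicate 3, and 0.0932 without CD4-negative replicate 1). NKT1 and type 1 had 0.00951 (without CD4-negative replicate 3; 0.0371 without CD4-positive replicate 2) to 0.515. TCR and immediate early genes had 0.000102 (without CD4-negative replicate 1) to 0.791, and thymocyte markers 0.00702 (without CD4-negative replicate 2; 0.00937 without CD4-positive replicate 3) to 0.847. Glycolysis had 0.00338 (without CD4-negative replicate 3; 0.0274 without CD4-positive replicate 2) to 0.970, oxidative phosphorylation 0.0152 (without CD4-negative replicate 2) to 0.892 and myeloid markers 0.0406 (without CD4-negative replicate 2) to 0.710. Without both libraries of a number, the call changed for interferon response (0.0531), NK cell and ILC markers (0.121) and oxidative phosphorylation (0.0493) by number 1, regulatory T cell markers (0.0970) by number 2, and lineage regulators (0.0608), glycolysis (0.0488) and NKT1 and type 1 (0.0166) by number 3. Gamma-delta markers (0.366 to 0.904), cytokines (0.274 to 0.964) and stroma and red cell markers (0.168 to 0.964) passed in none of these and changed direction in some, as did TCR and immediate early, thymocyte, glycolysis and oxidative phosphorylation lists. The cause was not tested.

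Genes that did not pass changed sign in some omissions: Cd8b1 (-1.08 to 0.11), Gata3 (-0.28 to 0.18), Ifng (-1.96 to 0.036), Runx3 (-0.013 to 0.44) and Tbx21 (-0.41 to 0.25; 0.17 by limma-voom with sample quality weights). The positive ends came without CD4-negative replicate 3 for Cd8b1 and Tbx21, as did the negative end of Runx3, and without CD4-negative replicate 1 for Ifng. Of the single-gene values 1259 kept direction and side of the threshold, 197 fell short of it, 98 passed it and 10 changed sign. The cause was not tested. Depth limits values near the 3 counts that a count of 0 allows (0.0555 to 0.0783 CPM).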

Other observations

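The tests in this part were chosen only after the results were seen, apart from the test of counting noise at a lower depth and the heat shock test. The SE beside a median over genes is their SD divided by the square root of their number. It is that of a mean and treats the genes as independent. Segments of the T cell receptor, which belong to no comparison above, were read as shares of the counts of their chain. Trav11 and its near-identical copy Trav11d, the segments of the invariant alpha chain, held 79.9 ± 2.14% of the Trav counts in CD4-positive and 81.2 ± 2.48% in CD4-negative libraries (exact permutation p = 0.7, n = 3 per group); the division between the copies varied between libraries and is uncertain. Among the beta segments Trbv13-2 held 25.3 ± 3.77% and 27.1 ± 1.06% of the Trbv counts, Trbv29 28.7 ± 2.6% and 20.6 ± 3.5%, Trbv13-1 16.9 ± 1.45% and 21.6 ± 2.01%, and Trbv13-3 7.79 ± 0.37% and 8.95 ± 0.92%. The libraries did not overlap for Trbv29, Trbv13-1 and Trbv13-3 (exact permutation p = 0.1 each, the smallest that 3 against 3 can give; 0.2 after adjustment over 6 segments).

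The splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05: the real split gave 27 genes and the highest other 0, and 12 lists against 6, so that 1 split, the real one, reached each count. The other splits gave 0 to 6 lists, so lists passed in mixed groups too. At an unadjusted p under 0.05 by edgeR the real split, with 567 genes, was not the highest. CD4-positive replicates 1 and 3 with CD4-negative replicate 3 against the rest gave 2272. CD4-positive replicate 1 with CD4-negative replicates 1 and 3 gave 1557, and with CD4-negative replicates 2 and 3 gave 641. The remaining splits gave 30 to 565.

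CD4-negative replicate 3 stood apart from the other libraries on the first component. A cubic trend in gene length and GC content held 3.69% of the variance of its deviations, which argues against such a trend as the whole cause; with all libraries thinned to the same total, the SD of its deviations over genes of at least 50 CPM was 1.51 times that of the highest other library, which argues against counting noise at a lower depth. Of 6552 genes of at least 20 CPM, 569 were at least 2-fold lower than in the other CD4-negative libraries and 142 at least 2-fold higher, while the median ratio of Trac, Tbx21, Il2rb, Klrb1c and Zbtb16 was 1.003, which argues against RNA of other cells as the cause of the lower genes. For the higher genes it stays open: 11 thymocyte markers had a median log2 ratio of 1.73 (SE 0.41) to the other CD4-negative libraries. Dntt stood at 27.1 against 2.88 and 1.37 CPM and Cd8b1 at 83.7 against 38.9 and 14.9 CPM. But CD4-positive replicate 3 had a median of 1.82 (SE 0.32) to the other CD4-positive libraries. That library did not stand apart on the first component (17.7), though it did on the second (-48.5, against -7.51 to 43.1 in the others). RNA quality and the state of the cells stay open, as untested.

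Genes known from innate cells (Lgals3, Ifitm1, Ncr1, Gzma) and the B cell gene Ighm had higher mean levels in the CD4-negative libraries. Of these genes Lgals3 and Ifitm1 passed the edgeR test over all genes, while Ncr1, Gzma and Ighm did not. Myeloid cells are argued against by Lyz2, at 0.565 CPM where Lgals3 was in excess by 40.2 CPM, and B cells by Igkc, at 0.337 CPM, and Cd79a, at 0.038 CPM, where Ighm was in excess by 46.4 CPM. Conventional NK cells in the CD4-negative sort remain a candidate source: the Trac ratio of CD4-negative to CD4-positive libraries was 0.941, too near 1 to decide on a small share, and the excess of Gzma over that of Eomes was 25.2, 24.1 and 141 in replicates 1, 2 and 3. The bound against this source compared replicates 1 and 2 only, and replicate 3 would have passed it. Among NK receptors, Klra3 (521 and 521 CPM in CD4-positive and CD4-negative libraries) and Klra7 (178 and 179 CPM) hardly differed, and Klra1 was at 387 and 339 CPM. But 21 of the 29 tested members of that list had a log2 difference below 0. A sort for iNKT cells would remove NK cells, but the gates are not given in the sources used here. A difference between the CD4-positive and CD4-negative subsets themselves stays open, as untested.

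Both replicate 1 libraries held Y-linked transcripts (466 counts in the lower of them) and high immediate early transcripts (Fos at 7.15 and 25.4 times and Dusp1 at 15.9 and 27 times the mean of the other CD4-positive and CD4-negative libraries), which may reflect cells of the same mice in both libraries of that number. T cell receptor stimulation stays open. Egr2 stood at 0.924 and 1.0 times those means, Irf4 at 0.999 and 0.885 times and Nr4a3 at 1.33 and 1.35 times. Only Nr4a1, at 8.82 and 15.8 times, was far above them. The median log2 ratios of these genes, 0.205 and 0.22 (SE 0.77 and 0.98), do not decide. For heat shock or handling stress, 5 heat shock genes had medians of 0.85 and 0.466 (SE 0.20 and 0.18) in the CD4-positive and CD4-negative group, while Hspa1a (8.05 and 12.4 times) and Hspa1b (4.89 and 8.85 times), outside those 5, go with this explanation. The lower median met the bound against it set beforehand (under 0.58, or 1.5-fold in either group), but by less than its SE, a condition applied only after the value was seen, so this explanation stays open too. The labels give no group that sets replicate 1 apart, so no biological explanation drawn from the design was tested.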
